A study of Mus musculus with 7 samples.

How the data were processed

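Single cell RNA sequencing of spleen T cells from C57BL/6 mice infected with the Armstrong strain of lymphocytic choriomeningitis virus was read from 7 libraries. The groups were taken from the labels: 2 libraries of total CD44high cells at day 7, and 1 GP66+ library each of wild type cells at day 7, Thpok-sufficient and Thpok-deleted cells at day 7, and Thpok-sufficient and Thpok-deleted cells at day 30. The labels name a CD4 gate for the wild type GP66+ library and none for the other GP66+ libraries. The deposited values are UMI counts per gene and barcode with no normalization. They come from the 10x 3' version 2 chemistry, per the labels' protocols, and were made with bcl2fastq 2.17 and Cell Ranger on mm10, per the submitters' processing notes. The version of Cell Ranger and which libraries had reads of 26 and 98 and which of 26 and 57 bases are not given in the sources used here. Each deposited matrix holds 27998 genes and 737280 barcodes per capture well, empty droplets included, and total CD44high replicate 1 joins 3 wells. The GP66+ libraries differ from each other in genotype or day and the total replicates in sex, so within each kind they came from different animals. How many animals gave each library, and whether a total and a GP66+ library share animals, is not stated. The p values measure the spread between these libraries, which may be technical in part. Gene coordinates are those of GENCODE vM21 on GRCm38, and 218 of 218 named genes had one.

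The groups, tests, gene lists, marker lists, rule for named genes and most alternatives were fixed before the data were examined. Values of some genes are not reported here; they remain in the list totals and in the counts over alternatives. A barcode was kept as a cell when its UMI total reached 10% of the 99th percentile of the top 3000 barcodes of its well, with at least 500 genes and at most 10% mitochondrial UMIs. Scrublet (scanpy 1.11.5, expected rate 6%) called 72 of 16114 cells doublets (0.447%). By the fixed rule for so few calls they were not used, so that keeping doublets is the same as the main setting. Cells were clustered with scanpy on 2000 variable genes, 20 principal components, 15 neighbours and Leiden resolution 0.8 (igraph 0.11.9), the total and the GP66+ libraries apart. A cluster took a name when 2 or more of the name's markers were among its 10 leading genes with a UMI in at least 20% of cells, 3 or more were 1.5-fold up with 20 CPM added, and no other name had 2. These naming thresholds were set after the data were seen. B-like and myeloid-like clusters, found in the total libraries alone, were left out of the sums, 188 cells (2.75%) of replicate 1 and 12 cells (0.561%) of replicate 2.

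CD4-like cells had a Cd4 UMI and no Cd8a or Cd8b1 UMI, and CD8-like cells a Cd8a or Cd8b1 UMI and no Cd4 UMI. They numbered 1439 and 3483 in total CD44high replicate 1, 550 and 1074 in replicate 2, and 1497 and 1319 cells of the wild type and Thpok-sufficient GP66+ libraries of day 7 were CD4-like. UMI counts were summed per library and class and tested with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr) and Benjamini-Hochberg adjustment at 0.05 in R 4.3.3. The comparison of CD8-like with CD4-like cells had the library as block, since both classes came from the same capture. The comparisons of genotype and day used all T cells of the 5 GP66+ libraries in 1 fit with both terms. Residual degrees of freedom were 1 for the lineage comparison and 2 for the other fits, and the biological coefficients of variation 0.0550, 0.209 and 0.227 for lineage, specificity and the fit of genotype and day. Standard errors are the absolute log2 fold change over the root of the F statistic. The 19 lists were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 5 members were tested, with an estimated correlation and fry as alternatives. Camera called 12 of 16 lists in the lineage, 10 of 15 in the specificity, 9 of 15 in the genotype and 6 of 15 in the day comparison. With an estimated correlation it called 0 in each, and fry called 0, 0, 3 and 3. The test with an estimated correlation rests on the 1 or 2 residual degrees of freedom, which leave it little power. Its lack of calls therefore decides little about a list.

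Genes named are Zbtb7b, 2 to 4 members per list and up to 12 genes per direction with the largest changes past the threshold and at least 20 CPM in the higher arm. For lineage and specificity these genes had no overlap between arms. For genotype they went the same direction at both days, and for day in both genotypes, so that single libraries of the arms may overlap. Where fewer than 5 passed, as for genes lower in GP66+ than in total CD4-like cells, others were added that did not pass, ranked there by the gap between the nearest libraries of the arms, a ranking set after the data were seen. For single libraries the rule took the 8 largest ratios per direction among genes with at least 50 UMIs. T cell receptor, immunoglobulin, haemoglobin, mitochondrial and ribosomal genes were not named by it, and Hbb-bs was named after its values were seen. Single-library ratios used TMM-scaled CPM with a prior count of 2, exact Poisson intervals at 95%, and 10000 random lists drawn from the 200 genes nearest in expression. CPM in the comparisons and ratios are TMM-scaled, and CPM of Zbtb7b per library, of sex-linked and haemoglobin genes and of empty droplets are scaled to library totals alone. Shares carry exact Clopper-Pearson intervals at 95%. Intervals and floors cover counting error only. An arm with no UMI was set at a floor of 3 counts over the whole arm, which is a single library in the single-library ratios. Genes with near-identical copies (Hspa1a, Hspa1b, Klra7, Ly6c1, Ly6c2, Amd2, Ifi204) are uncertain, since reads may be split between copies.

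On counts simulated from these libraries, 200 genes with a mean of at least 20 CPM were changed. The lineage comparison recovered 100% of genes changed 2-fold. The specificity comparison recovered 38.8% (26 of 67), the genotype comparison 41.8% (28 of 67) and the day comparison 53.7% (36 of 67) at 2-fold, and each recovered 100% at 4-fold and 8-fold. Of unchanged genes 5 of 10002, 3 of 10064, 3 of 10612 and 5 of 10612 were called. The counts were drawn with the dispersion of the fit itself and no added batch effect. These rates therefore hold only as far as the libraries follow that model, and the recovery does not cover genes of lower expression. Replicate pairs differed beyond sampling noise, with a chi-square per degree of freedom of 11.0 for CD4-like and 23.7 for CD8-like total cells and 51.6 for the GP66+ pair of day 7. The alternatives were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, at least 1000 genes per cell, sums thinned to the smallest, a gate of 2 UMIs, subsets of cells, each library left out, other scalings and prior counts for ratios, and other thinning depths and resolutions for shares. Chosen after seeing the data were a fit without the cells that Scrublet called, a covariate that sets total replicate 1 and the wild type GP66+ library against the others, clustering of each library alone, and a test of the genotype by day interaction. Tables were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.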

Results

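Gene expression in single spleen T cells was measured with droplet 3' RNA sequencing in 7 libraries from mice infected with the Armstrong strain of lymphocytic choriomeningitis virus. Total activated T cells, marked by high CD44, came from wild type mice at day 7, with CD4+ and CD8+ cells sorted apart and pooled in equal parts (2 libraries, replicate 1 and replicate 2). Virus-specific helper cells were sorted with a tetramer of the class II molecule I-Ab holding the viral peptide GP66. Of these GP66+ cells, 1 library came from wild type mice at day 7. The other 4 came from mice in which Cre recombinase under the Ox40 promoter marked activated T cells with a yellow reporter and, where both alleles were floxed, deleted Zbtb7b, the gene of the transcription factor Thpok. They form 1 Thpok-sufficient and 1 Thpok-deleted library at day 7 and the same pair at day 30.

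Cells kept numbered 6845 and 2139 in total CD44high replicates 1 and 2, and 2212 in the wild type, 2138 in the Thpok-sufficient and 1319 in the Thpok-deleted GP66+ library of day 7. At day 30, 725 Thpok-sufficient and 736 Thpok-deleted cells were kept. The cells held 32985497, 12106559, 14296566, 12467348, 8844794, 1551772 and 2141556 unique molecular identifiers (UMIs) in the same order. The median cell held between 2017 UMIs in the day 30 Thpok-sufficient library and 5900 in the day 7 Thpok-deleted library.

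Zbtb7b (ENSMUSG00000028042; chromosome 3, 89377644 to 89394776, minus strand, GRCm38) followed the genotype labels. It stood at 27.1 (95% interval 24.5 to 30.0) CPM (UMI counts scaled to a common library total) in the wild type, 31.4 (95% interval 28.3 to 34.6) in the Thpok-sufficient and 20.6 (95% interval 14.1 to 29.1) in the day 30 Thpok-sufficient GP66+ library. Each Thpok-deleted library held 1 Zbtb7b UMI. With the TMM factors of edgeR, which also scale CPM in the comparisons below, the ratio of Thpok-sufficient to Thpok-deleted cells was 289 at day 7 (counting interval 51.8 to 11405) and 51.2 at day 30 (counting interval 9.19 to 2022). Total CD44high cells held, scaled to library totals alone, 23.9 CPM in replicate 1 and 29.5 in replicate 2. The 3' untranslated part of the main transcripts, 89377644 to 89379528, lies in the last exon, which the tags of this chemistry cover. Which exons are floxed is not given in the sources used here.

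The first comparison set CD8-like against CD4-like cells within the 2 total CD44high libraries, and so gives the difference between the 2 lineages in the same infection and capture. Of the lists, 17 of 18 CD8 lineage and cytotoxic, 14 of 19 Th1 and all 20 cell cycle genes were higher in CD8-like cells, and all 18 genes of the list of follicular helper (Tfh) cells, which help B cells, and 7 of 8 CD4 helper genes were higher in CD4-like cells. Camera called 12 of 16 lists, and 0 with an estimated correlation (lowest adjusted p = 0.306). The latter test had little power, since it rests on the residual degrees of freedom. Of 10202 genes tested with edgeR and the library as block, 1810 were higher in CD8-like and 1871 in CD4-like cells, with 1 residual degree of freedom. DESeq2 called 752 and 585, and edgeR without the block 522 and 620. Cd4, Cd8a and Cd8b1 define the classes and are no result.

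Of the CD8 lineage and cytotoxic list, 17 of 18 tested genes were higher in CD8-like cells, also 17 when adjusted over the list alone (camera adjusted p = 6.0e-90; adjusted p = 0.306 with an estimated correlation). Gzma, a granzyme, averaged 5257 ± 1926 CPM (SD, n = 2) in CD8-like and 84.0 ± 57.6 CPM (SD, n = 2) in CD4-like cells (log2 fold change 6.00 ± 0.10 (SE), adjusted p = 1.2e-22). The lectin-like receptors Klrk1, Klrd1 and Klre1 had log2 fold changes of 4.95, 4.02 and 5.27. Klra7, of a receptor family with close copies, held 2 UMIs in all CD4-like cells and 33.8 CPM in CD8-like cells, a ratio of 170.2 (counting interval 47.1 to 1405). Other large differences in this direction were log2 fold changes of 5.47 for Itgax, 4.85 for S1pr5, 4.19 for Zeb2 and 3.97 for Cx3cr1. Wdr95, As3mt and Samd3, whose work in T cells is less defined, had log2 fold changes of 5.59, 4.55 and 3.95.

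Of the Th1 list, the programme of inflammatory helper and killer cells, 14 of 19 genes were higher and 1 lower in CD8-like cells, the same numbers adjusted over the list alone (camera adjusted p = 2.3e-21; adjusted p = 0.361 with an estimated correlation). Log2 fold changes were 3.53 for the chemokine Ccl5 and 3.01 for the surface marker Ly6c2. All 20 cell cycle genes were higher in CD8-like cells, by moderate amounts such as 1.15 for Stmn1 and 1.10 for the cyclin Ccnb2 (camera adjusted p = 3.0e-18; adjusted p = 0.306 with an estimated correlation). NK markers gave 4 of 5 genes higher in CD8-like cells and myeloid markers 5 of 8, among them Itgam (2.61) and Tyrobp (2.38). B cell markers gave 1 of 5 higher (Cd79b, 1.40) and 1 lower (Cd74, of the class II pathway). Erythroid markers gave 2 of 4 higher, and of the gamma-delta T markers only Cd163l1 could be tested and was higher.

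All 18 Tfh list genes were higher in CD4-like cells, also 18 when adjusted over the list alone (camera adjusted p = 1.8e-75; adjusted p = 0.306 with an estimated correlation). The chemokine receptor Cxcr5, which leads cells to B cell follicles, averaged 82.4 ± 26.1 CPM (SD, n = 2) in CD4-like and 4.76 ± 0.0220 CPM (SD, n = 2) in CD8-like cells (log2 fold change -4.21 ± 0.14 (SE), adjusted p = 6.5e-17). Il21, a cytokine for B cells, had a log2 fold change of -4.53. Izumo1r, a folate receptor family member, Tox2 and Maf, both transcription factors of Tfh cells, had -3.94, -4.21 and -3.55. Of the CD4 helper lineage list, 7 of 8 genes were higher in CD4-like cells (also 7 adjusted over the list alone; camera adjusted p = 8.5e-19; adjusted p = 0.306 with an estimated correlation). They include Zbtb7b (log2 fold change -1.90 ± 0.13 (SE), adjusted p = 4.1e-11), the CD40 ligand Cd40lg (-3.93), Tox (-2.24) and the costimulator Icos (-1.96). The tumour necrosis factor family members Tnfsf8 and Tnfrsf4 had -3.61 and -3.60. Sostdc1 and Angptl2, secreted proteins, Padi4, an enzyme that converts arginine, the ATP receptor P2rx7 and the Rab regulator Tbc1d4 had log2 fold changes of -5.09, -4.97, -4.96, -4.43 and -3.73.

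Memory and lymphoid homing genes went both ways, 5 higher in CD8-like cells and 8 higher in CD4-like cells of 17 (5 and 9 adjusted over the list alone; camera adjusted p = 1.7e-04; adjusted p = 0.306 with an estimated correlation). The transcription factors Tcf7 (-2.72) and Id3 (-3.06) and the homing receptor Ccr7 (-2.01) were higher in CD4-like cells, and the transcription factor Eomes (2.91) in CD8-like cells. Of the Treg list, 5 of 6 genes were higher in CD4-like cells, Foxp3 (-2.24) and Ikzf2 (-2.18) among them (camera adjusted p = 7.7e-13; adjusted p = 0.306 with an estimated correlation). TCR signalling and early response genes gave 6 of 11 (8 adjusted over the list alone), with -2.99 for Egr2, dissociation stress genes 6 of 10, and interferon response genes 9 of 15 with -2.05 for Rsad2, all higher in CD4-like cells, while 1 interferon gene was higher in CD8-like cells. Their camera adjusted p values were 4.6e-04, 0.0357 and 2.6e-05, and 0.306, 0.378 and 0.306 with an estimated correlation. Inhibitory receptors split into 5 higher in CD8-like cells, such as Havcr2 (2.59), and 3 higher in CD4-like cells, such as Cd200 (-3.30). Apoptosis regulators split into 5 and 4, with 1.15 for Pmaip1 and -0.98 for Bcl2. Glycolysis genes gave 8 of 16 higher in CD4-like cells, such as Tpi1 (-0.86), and 1 in CD8-like cells, the glucose transporter Slc2a3 (1.53). Of 4 tested Th2 and Th17 genes, 3 were higher in CD4-like cells, and 4 when adjusted over the list alone.

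GP66+ cells with intact Thpok were then compared with CD4-like cells of the total libraries at day 7, which contrasts helper cells of 1 viral specificity with activated helper cells of mixed specificity. The TCR signalling and early response list, with 4 of 11 genes higher in GP66+ cells, and the dissociation stress list, with 2 of 11, held the most calls of any list, and camera called 0 of 15 lists with an estimated correlation (lowest adjusted p = 0.206). Of 10264 genes tested with edgeR, 49 were higher in GP66+ cells and 0 lower, against 699 and 619 at an unadjusted p under 0.05. DESeq2 called 128 and 39. The counts rest on single libraries: without total replicate 1 both were 0, without total replicate 2 they were 4 and 3, without the wild type GP66+ library 126 and 47, and without the Thpok-sufficient library 322 and 340.

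Of the TCR signalling and early response list, 4 of 11 genes rose (7 adjusted over the list alone; camera adjusted p = 2.6e-26; adjusted p = 0.206 with an estimated correlation). These were the nuclear receptors Nr4a1, Nr4a2 and Nr4a3, with log2 fold changes of 4.05, 4.97 and 3.98, and the retention receptor Cd69 (2.54). Nr4a1 averaged 226 ± 29.6 CPM (SD, n = 2) in GP66+ and 13.9 ± 3.23 CPM (SD, n = 2) in total CD4-like cells (log2 fold change 4.05 ± 0.21 (SE), adjusted p = 0.00859). Of the dissociation stress list, which holds genes that tissue handling can induce, 2 of 11 rose, the phosphatase Dusp1 (4.09) and the AP-1 factor Junb (2.69), and 8 when adjusted over the list alone (camera adjusted p = 1.2e-26; adjusted p = 0.206 with an estimated correlation). Fos had a log2 fold change of 4.28 and did not pass (adjusted p = 0.0873). Among the largest changes were the growth factor Areg (log2 fold change 5.77 ± 0.26 (SE), adjusted p = 0.00859), the nuclear factor kappa B regulators Tnfaip3 (4.09) and Nfkbiz (3.01), the stress phosphatase subunit Ppp1r15a (3.60), the G protein regulator Rgs2 (3.51), the AP-1 factor Fosl2 (3.13), the chemokine Cxcl10 (3.06) and Mir155hg, host of a microRNA (2.98). The inhibitory receptor Ctla4, on both the Treg and the inhibitory receptor lists, rose (log2 fold change 2.14 ± 0.19 (SE), adjusted p = 0.0213), as did Tnfsf8 of the Tfh list (log2 fold change 1.32 ± 0.16 (SE), adjusted p = 0.0441).

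With edgeR no gene passed in the other direction, against 39 with DESeq2. Among the larger differences there were -3.53 for the membrane protein Ifitm1 (adjusted p = 0.0985), -2.93 for the interleukin 7 receptor Il7r (adjusted p = 0.179), -2.61 for Gzma (adjusted p = 0.155), -1.66 for Id3 (adjusted p = 0.114) and -1.61 for the redox regulator Txnip (adjusted p = 0.0524). Foxp3, the regulatory T cell factor, held 3 UMIs in GP66+ cells, and the ratio of total CD4-like to GP66+ cells was 35.9 (counting interval 12.3 to 174; adjusted p = 0.129). Zbtb7b did not pass (log2 fold change -0.62 ± 0.23 (SE), adjusted p = 0.362), nor did the costimulator Icos (adjusted p = 0.0521) or Cd40lg (0.99, adjusted p = 0.0760). Adjusted over the list alone, 5 of 17 CD8 lineage and cytotoxic genes, 8 of 17 memory and lymphoid homing genes, 4 of 15 interferon response genes, 3 of 6 B cell markers and 3 of 7 myeloid markers were lower in GP66+ cells. Camera gave adjusted p values of 2.0e-06, 1.4e-04, 5.8e-06, 4.9e-04 and 0.00103 for these lists, and 0.206, 0.283, 0.433, 0.206 and 0.283 with an estimated correlation. No member passed over all genes in the CD4 helper (9 tested), Th1 (19), Th2 and Th17 (4), cell cycle (20), glycolysis (16), apoptosis (13), NK (3) or erythroid (4) lists. Adjusted over the list alone, 2 CD4 helper, 4 Th1, 3 Tfh, 1 Th2 and Th17, 1 glycolysis and 4 apoptosis genes were higher, and 4 Th1, 2 Tfh, 1 NK and all 4 erythroid genes lower. Empty droplets held Gzmb at 830 and 1365 CPM in the total and 138 and 214 CPM in the GP66+ libraries. Lyz2 stood there at 78.8 and 65.1 against 9.22 and 48.2 CPM, while Cd74 and Hbb-bs did not part the libraries this way. RNA from outside the cells was not tested as a source of the lower cytotoxic, B cell, myeloid and erythroid genes. Camera gave adjusted p = 4.9e-04 for cell cycle, 0.00318 for glycolysis and 0.00107 for apoptosis genes, all towards GP66+ cells, or 0.475, 0.475 and 0.206 with an estimated correlation.

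The comparison of Thpok-deleted with Thpok-sufficient GP66+ cells over both days asks what Thpok maintains in helper cells after their activation. In cells without Thpok 14 of 19 genes of the CD8 lineage and cytotoxic list and 7 of 19 of the Th1 list were higher, and 3 of 9 helper genes, Zbtb7b itself among them, and 3 of 18 Tfh genes were lower. Camera called 9 of 15 lists, and 0 with an estimated correlation (lowest adjusted p = 0.0636). Of 10812 genes tested with edgeR and day as covariate, 79 were higher and 41 lower in Thpok-deleted cells, against 945 and 967 at an unadjusted p under 0.05. DESeq2 called 258 and 219. With any 1 library left out, the fit of genotype and day keeps 1 residual degree of freedom. Without the day 7 Thpok-deleted or either day 30 library, that is the difference between the wild type and Thpok-sufficient libraries of day 7. The number of residual degrees of freedom therefore does not set the fits below apart. Counts were 252 and 165 without the wild type library, 34 and 12 without the day 7 Thpok-sufficient library, and 0 and 0 without the day 7 Thpok-deleted, the day 30 Thpok-sufficient or the day 30 Thpok-deleted library, fits that keep 1 residual degree of freedom.

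Of the CD8 lineage and cytotoxic list, 14 of 19 genes rose and 0 fell, and all 19 rose when adjusted over the list alone (camera adjusted p = 5.5e-69; adjusted p = 0.0636 with an estimated correlation). Gzmk, a granzyme, averaged 167 ± 99.7 CPM (SD, n = 2) in Thpok-deleted and 12.9 ± 5.47 CPM (SD, n = 3) in Thpok-sufficient cells (log2 fold change 3.88 ± 0.15 (SE), adjusted p = 0.00899). Gzma (log2 fold change 5.99 ± 0.81 (SE), adjusted p = 0.04998) and Gzmm (3.75) rose with it. Cd8a, which encodes the CD8 alpha chain, averaged 24.3 ± 7.93 CPM (SD, n = 2) against 1.29 ± 0.821 CPM (SD, n = 3) (log2 fold change 4.84 ± 0.40 (SE), adjusted p = 0.0222). Eomes, a transcription factor of killer and memory cells, rose (log2 fold change 5.09 ± 0.32 (SE), adjusted p = 0.0171), and so did Klrg1 (4.61), Klrd1 (3.62) and the fractalkine receptor Cx3cr1 (4.13). NK markers gave 2 of 4 genes, Eomes and Klre1 (3.84). Itgam, the 1 of 8 myeloid markers that rose (3.03), and Itgax (6.61) encode integrin chains. Wdr95 (log2 fold change 7.32 ± 0.49 (SE), adjusted p = 0.0171), the kinase Lrrk1 (4.02) and the secreted protein Fgl2 (3.79) were among the other large increases. Of the Th1 list, 7 of 19 genes rose (14 up and 2 down adjusted over the list alone; camera adjusted p = 2.9e-22; adjusted p = 0.0636 with an estimated correlation). They include Ccl5 (log2 fold change 3.50 ± 0.23 (SE), adjusted p = 0.0171), Ly6c2 (2.33) and the chemokine receptor Cxcr6 (1.67).

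Of the CD4 helper lineage list, 3 of 9 genes fell (6 adjusted over the list alone; camera adjusted p = 1.6e-10; adjusted p = 0.263 with an estimated correlation), namely Zbtb7b itself, Cd40lg (log2 fold change -2.21 ± 0.22 (SE), adjusted p = 0.0335) and Icos (log2 fold change -1.14 ± 0.14 (SE), adjusted p = 0.0466). Zbtb7b held 2 UMIs over both Thpok-deleted libraries, a ratio of 151 (counting interval 41.8 to 1247; adjusted p = 0.0171). The deletion itself lowers Zbtb7b, so part of the CD4 helper list's counts and camera value was fixed in advance. That list was not tested without Zbtb7b. Of the Tfh list, 3 of 18 genes fell and 14 when adjusted over the list alone (camera adjusted p = 6.1e-19; adjusted p = 0.289 with an estimated correlation). Cxcr5 fell from 60.7 ± 7.16 CPM (SD, n = 3) to 6.45 ± 1.44 CPM (SD, n = 2) (log2 fold change -3.31 ± 0.25 (SE), adjusted p = 0.0173). The others were Icos and Ascl2, a transcription factor that starts the Tfh programme, which had no UMI in the Thpok-deleted libraries. Il6ra, an interleukin 6 receptor chain that Tfh cells use, had a log2 fold change of -3.28. The interferon-inducible Ifi204, which has close relatives, had -4.83, the small MAF factor Maff -2.47 and Smco4, a membrane protein, -2.39. Further decreases were -1.88 for Ccdc141, -1.83 for Adk, -1.80 for Trib2 and -1.72 for Tesc. Oasl2 of the interferon response list fell (adjusted p = 0.0498) and was the 1 gene of 15 that passed there.

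In the lists that follow at most 1 member passed over all genes, although median log2 fold changes were 5.11 for erythroid markers, 2.04 for inhibitory receptors, -1.87 for B cell markers and -1.56 for Th2 and Th17 genes. Of the memory and lymphoid homing list only Eomes passed, and Tcf7 did not (log2 fold change -2.42 ± 0.35 (SE), adjusted p = 0.0604). Inhibitory receptors gave 0 of 9 past the threshold but 5 up and 1 down adjusted over the list alone (camera adjusted p = 2.1e-05; adjusted p = 0.218 with an estimated correlation). Havcr2 had a log2 fold change of 2.94 (adjusted p = 0.0604) and Lag3 of 2.37 (adjusted p = 0.109). Cell cycle genes gave 0 of 20, and 12 up adjusted over the list alone (camera adjusted p = 2.6e-12; adjusted p = 0.289 with an estimated correlation). TCR signalling and early response genes gave 0 of 11 and dissociation stress genes 0 of 12, and 5 down in each adjusted over the list alone (camera adjusted p = 6.6e-04 and 2.1e-05; adjusted p = 0.310 and 0.289 with an estimated correlation). Treg genes gave 0 of 8, Th2 and Th17 genes 0 of 4 and apoptosis regulators 0 of 13. Of 16 glycolysis genes only Slc2a3 rose (log2 fold change 1.72 ± 0.23 (SE), adjusted p = 0.0498). B cell markers gave 0 of 6, and when adjusted over the list alone 1 higher (Cd79b) and 3 class II genes lower, H2-Ab1 (-2.77) and H2-Eb1 (-2.52) among them (camera adjusted p = 5.3e-04; adjusted p = 0.245 with an estimated correlation). Erythroid markers gave 0 of 4 and gamma-delta T markers 0 of 1. Hbb-bs, a haemoglobin gene, stood at 2256 CPM in the day 30 Thpok-deleted library and at most 2.09 in the other GP66+ libraries.

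**Figure D1:**
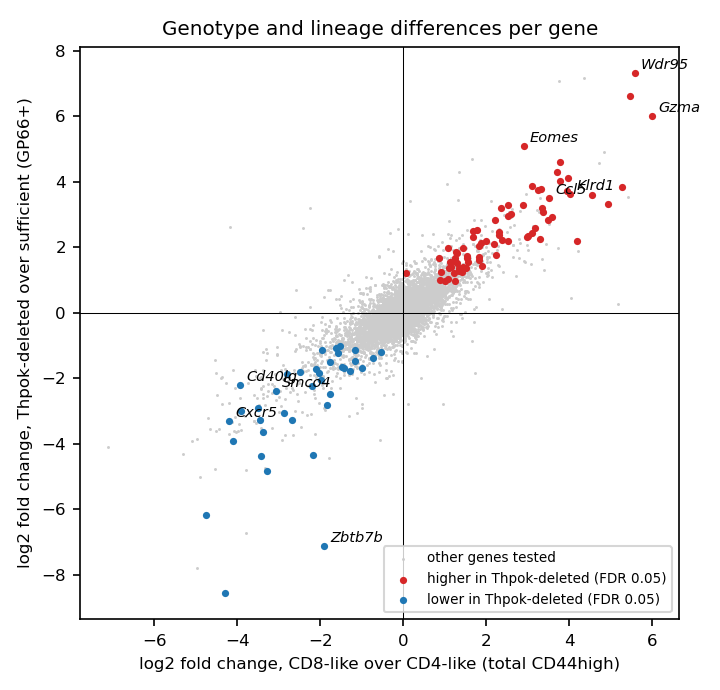
Each point is 1 of 9701 genes tested in both comparisons, with the log2 fold change of CD8-like over CD4-like total cells on the horizontal axis and of Thpok-deleted over Thpok-sufficient GP66+ cells on the vertical axis. Red points are 76 genes higher and blue points 37 genes lower in Thpok-deleted cells at an adjusted p under 0.05, of which 75 were called higher in CD8-like and 37 higher in CD4-like cells. Left out are T cell receptor, immunoglobulin, haemoglobin, mitochondrial and ribosomal genes, and genes with Gm, Rik or clone names. Cd4, Cd8a, Cd8b1 and the sex list are also left out. The blue points include Zbtb7b, which the deletion itself lowers.

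Day 30 GP66+ cells were compared with day 7 cells over both genotypes, which follows virus-specific helper cells from the effector to the memory phase. Of the lists, 19 of 20 cell cycle and 9 of 16 glycolysis genes fell, and 7 of 17 memory, 7 of 11 early response and 8 of 12 stress genes rose. Camera called 6 of 15 lists, and 0 with an estimated correlation (lowest adjusted p = 0.341). With edgeR and genotype as covariate, 1078 of 10812 genes rose and 1283 fell. Without the wild type library the counts were 1440 and 1465, without the day 7 Thpok-sufficient library 536 and 461, and 0 and 0 without the day 7 Thpok-deleted or either day 30 library. Day 30 cells held fewer UMIs than day 7 cells, and the stricter limit of 1000 genes per cell gave 291 and 289.

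Of 20 cell cycle genes, 19 fell, also 19 adjusted over the list alone (camera adjusted p = 1.8e-25; adjusted p = 0.341 with an estimated correlation). Birc5, needed for cell division, averaged 173 ± 62.3 CPM (SD, n = 3) at day 7 and 27.2 ± 24.8 CPM (SD, n = 2) at day 30 (log2 fold change -3.01 ± 0.39 (SE), adjusted p = 0.0137). The spindle factor Tpx2, the cyclins Ccnb1 and Ccnb2 and the ubiquitin enzyme Ube2c had log2 fold changes of -3.71, -3.21, -3.17 and -3.01. Other mitotic genes among the largest decreases were -3.30 for Apitd1, -3.09 for Hmmr, -2.89 for Cenpf and -2.87 for Cdca3. Of the glycolysis list, 9 of 16 fell and 10 adjusted over the list alone (camera adjusted p = 4.6e-06; adjusted p = 0.341 with an estimated correlation), such as -2.63 for Tpi1, -1.61 for Pkm and -1.34 for Ldha. Other decreases were -2.93 for Gzmb, -3.07 for the annexin Anxa2 and -2.94 for the transcription factor Zbtb32.

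Of the dissociation stress list, 8 of 12 rose and all 12 adjusted over the list alone (camera adjusted p = 7.4e-16; adjusted p = 0.341 with an estimated correlation). Atf3 (log2 fold change 5.54 ± 0.30 (SE), adjusted p = 0.00757), Btg2 (2.52), Jun (2.47) and Hspa1b (4.08), a heat shock gene with a near-identical copy, were among them. Of the TCR signalling and early response list, 7 of 11 rose (7 adjusted over the list alone; camera adjusted p = 5.9e-09; adjusted p = 0.341 with an estimated correlation), with log2 fold changes of 3.69 for Nr4a3, 2.72 for Nfkbid, 2.57 for Nr4a2 and 2.03 for Nr4a1. The stress and early response lists also differed between the wild type and the Thpok-sufficient library of day 7, with median log2 ratios of -0.72 and -0.44. Handling of the cells cannot be told apart from day here. Of the memory and lymphoid homing list, 7 of 17 rose and 9 adjusted over the list alone (camera adjusted p = 4.2e-04; adjusted p = 0.341 with an estimated correlation). Il7r, the receptor for the survival cytokine interleukin 7, averaged 321 ± 255 CPM (SD, n = 2) at day 30 and 10.6 ± 5.57 CPM (SD, n = 3) at day 7 (log2 fold change 4.91 ± 0.72 (SE), adjusted p = 0.0161), and Ly6c1, Ccr7 and the repressor Bach2 had 2.80, 1.80 and 1.77. C2cd4b held 1 UMI at day 7 and 39.8 CPM at day 30, a ratio of 1492 (counting interval 268 to 58943; adjusted p = 0.00882). Further increases were 5.97 for the opioid precursor Penk, 5.28 for the transcription factor Cebpb, 4.90 for Nrn1, 4.65 for the GTPase Rhob, 3.73 for the transcription factor Klf9, and 4.42 for Adam28, 4.14 for Vwa1 and 3.73 for Amd2. C2cd4b, Penk and Nrn1 stood at 5.97, 1.49 and 6.72 CPM in the Thpok-sufficient and 73.7, 42.0 and 62.5 CPM in the Thpok-deleted library of day 30, so that their increases lie mostly in the Thpok-deleted library.

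Lineage lists moved in part. Of the CD8 lineage and cytotoxic list 2 of 19 rose, Klrk1 (2.60) and Fasl (2.19), and 3 fell, Gzmk (-1.28) among them (camera adjusted p = 0.988). Th1 genes gave 3 up, with 1.32 for Ccl5, and 1 down, the chemokine receptor Cxcr3, of 19. CD4 helper genes gave 2 up of 9, Cd40lg (1.82) and Satb1 (1.14). Tfh genes gave 2 up of 18, Bcl6 (2.63) and Il6st (1.75), and 1 down, Sh2d1a (-1.05). Interferon response genes gave 2 up, with 1.88 for Irf7, and 6 down, with -1.42 for Ifi27l2a, of 15. Tigit (1.87) was the 1 inhibitory receptor of 9 that rose, Lrrc32 (4.44) the 1 Treg gene of 8, and of 13 apoptosis regulators Bbc3 rose (1.82) and 3 fell, with -1.45 for Bak1. Class II genes of the B cell markers rose, 3 of 6, with 2.15 for H2-Eb1, 2.12 for Cd74 and 2.06 for H2-Aa, and of the myeloid markers Apoe rose (2.96) and Itgam fell (-3.00). Of the B cell markers camera gave adjusted p = 0.0450 (adjusted p = 0.341 with an estimated correlation). Of 4 Th2 and Th17 genes Rora rose, and NK, erythroid and gamma-delta T markers gave 0 of 4, 0 of 4 and 0 of 1, with medians of 1.19, 7.08 and 2.13. Zbtb7b did not pass (log2 fold change -0.13 ± 0.35 (SE), adjusted p = 0.811).

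**Figure D2:**
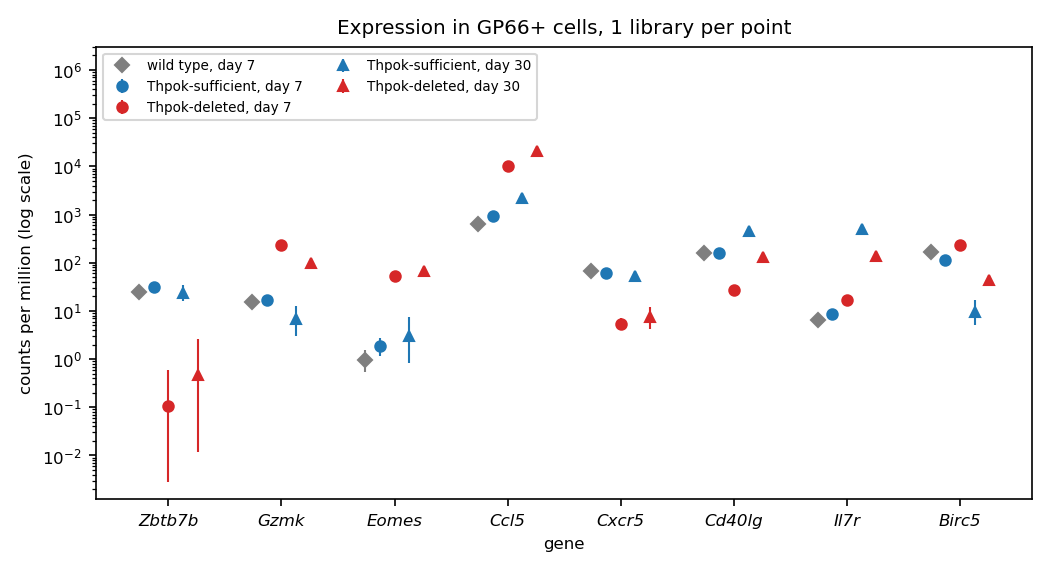
CPM on a log scale for 8 genes in the 5 GP66+ libraries, 1 point per library, with bars for exact Poisson 95% intervals that cover counting error only. Gzmk, Eomes and Ccl5 are higher and Zbtb7b, Cxcr5 and Cd40lg lower in the Thpok-deleted library than in the sufficient library of the same day.

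Within each day a single library stands for each genotype, so the following ratios describe these libraries and were not tested, and their intervals cover counting error only. At day 7 the largest increases in Thpok-deleted over Thpok-sufficient cells were log2 ratios of 6.68 for Wdr95, 5.29 for Itgax, 5.15 for Gzma, 4.73 for Cd8a, 4.63 for Eomes, 4.40 for Klrd1, 3.99 for Klrk1 and 3.92 for Klrg1. Beside Zbtb7b itself, with 391 UMIs in Thpok-sufficient and 1 in Thpok-deleted cells, the largest decreases were -7.30 for Sostdc1, -5.33 for the cytokine Tnfsf11, -5.26 for the protease Ctse, -5.25 for Fam43a, -5.17 for Il21 and -5.04 for Tnfsf8. Ctse was also at least 4-fold lower in the wild type than in the Thpok-sufficient library of day 7, which both have intact Thpok. Its decrease is therefore not one of genotype alone. Padi4, at 0 UMIs in Thpok-deleted cells, was at least 88.1-fold lower against a floor of 3 counts in that library. At day 30 Gzma held 1 UMI in Thpok-sufficient and 2258 in Thpok-deleted cells, a ratio of 1411 (counting interval 253 to 55748). The chemokines Ccl3 and Ccl4 and Gzmb had log2 ratios of 5.58, 5.08 and 5.43, the chemokine Xcl1 a ratio of 65.2 (counting interval 22.3 to 316), and Ccl1 and S1pr5 were at least 18.1-fold and 14.2-fold higher against the floor. Among genes with at least 50 UMIs, which leaves out Zbtb7b, decreases at day 30 were smaller, -2.99 for Ramp3, -2.79 for Cxcr5, -2.49 for Il6ra, -2.43 for Egr2, -2.34 for Maff, -2.27 for Smco4 and -2.08 for Cd2ap.

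List medians describe the same libraries, each beside its percentile among 10000 random lists of like size and expression. The CD8 lineage and cytotoxic list had a median log2 ratio of 3.02 at day 7, 3.24 against the wild type library and 3.00 at day 30, at percentile 100 in each. The Tfh list had medians of -3.01, -2.69 and -0.94 in the same order, at percentile 0. With 2 members that had no UMI in Thpok-deleted cells set at the floor, the day 7 medians were -2.97 and -2.51. The Th1 list stood at 1.28 and 1.54, and the cell cycle list at 0.98 and 1.99 at day 7 and day 30, and at 1.31 and 0.55 against the wild type library, all at percentile 100, with 4 of 20 cell cycle genes lower than in the wild type library. Erythroid markers had a median of 10.60 (percentile 100) for Thpok-deleted over Thpok-sufficient cells at day 30, or 9.89 with 3 members that had no UMI in an arm set at the floor. Between the wild type and the Thpok-sufficient library of day 7, the CD8 lineage and cytotoxic median was -0.17 (percentile 3.54) and the Tfh median -0.10 (percentile 9.86). Other lists stood at extreme percentiles between these 2 libraries, which both have intact Thpok, with 0.37 (percentile 100) for cell cycle, 0.28 (percentile 100) for glycolysis, -0.72 (percentile 0) for dissociation stress, -0.38 (percentile 0) for memory and lymphoid homing and -0.44 (percentile 0.0400) for TCR signalling and early response genes, as wild type over Thpok-sufficient cells. From day 7 to day 30 the cell cycle list had a median of -3.13 in Thpok-sufficient and -2.30 in Thpok-deleted cells, at percentile 0 in both, and the dissociation stress list 1.74 (percentile 100) and 2.34 (percentile 100). The CD8 lineage and cytotoxic list had -0.63 in Thpok-sufficient cells, but 0.20 with the wild type library as the day 7 value. Il7r (5.75), Atf3 (5.30) and Cebpb (4.68) led the day 30 increases in Thpok-sufficient cells, and Gzmb (-4.76) and Ccnb2 (-4.23) the decreases. In Thpok-deleted cells Hspa1a (6.80) and Sostdc1 (5.79) were among the largest increases, C2cd4b and Penk were at least 226-fold and 129-fold higher, and Mxd3 (-3.85) and Ifitm1 (-3.79) were among the largest decreases. A test of whether the genotype difference itself differs between days called 0 of 11338 genes with edgeR, with 759 at an unadjusted p under 0.05 and 1 residual degree of freedom.

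Shares of cells with a UMI were read after thinning each cell to 1000 UMIs, which left out 11 Thpok-sufficient and 4 Thpok-deleted cells of day 30 and 0 elsewhere. Gzmb was found in 7.91% (95% interval 6.82 to 9.12) of wild type, 7.76% (95% interval 6.67 to 8.98) of Thpok-sufficient and 58.4% (95% interval 55.7 to 61.1) of Thpok-deleted cells at day 7, and in 0.420% (95% interval 0.0867 to 1.22) and 22.8% (95% interval 19.8 to 26.0) at day 30. Unthinned, these shares were 14.9%, 14.8%, 87.5%, 1.24% and 35.7%. UMIs from outside the cells, taken at the 99th percentile of UMIs per barcode there, would give a Gzmb UMI to at most 0.555%, 0.390%, 1.38%, 0.176% and 1.32% of cells in the same order, and a Cxcr5 or Runx3 UMI to at most 0.350% and 0.493% in any library. The CD8-like cells of the total libraries held Gzmb in 56.0% and 69.3% after thinning. Cxcr5 was found in 7.87% (95% interval 6.78 to 9.07), 5.14% (95% interval 4.25 to 6.17) and 0.607% (95% interval 0.262 to 1.19) at day 7 and 5.04% (95% interval 3.56 to 6.91) and 0.410% (95% interval 0.0846 to 1.19) at day 30 in the same order, or 33.4%, 25.9%, 3.03%, 8.97% and 2.04% unthinned. CD8-like total cells held Cxcr5 in 0.459% and 0.279% after thinning. The median depths before thinning were 4195 and 5286.5 UMIs in those CD8-like cells and 5900 and 2440 in the Thpok-deleted libraries. Thinned shares of Runx3, a transcription factor of the CD8 lineage, were 6.10%, 6.74% and 13.6% at day 7 and 8.12% and 19.9% at day 30, and unthinned 29.7%, 31.0%, 57.4%, 16.6% and 40.8%. Il7r was found in 34.0% of Thpok-sufficient and 9.97% of Thpok-deleted cells at day 30 after thinning, or 51.0% and 23.8% unthinned, and in at most 1.52% of thinned cells in the day 7 GP66+ libraries. UMIs from outside the cells would give an Il7r UMI to at most 2.37% of Thpok-sufficient and 0.560% of Thpok-deleted cells at day 30. Cd8b1, the CD8 beta chain, was found in 7.35% (95% interval 6.00 to 8.90) of thinned Thpok-deleted cells at day 7 and 2.19% (95% interval 1.25 to 3.53) at day 30, against 1.26% and 0.980% in Thpok-sufficient cells and 78.6% and 71.9% in CD8-like total cells, and unthinned in 29.1% and 7.34% of Thpok-deleted cells. CD8-like cells hold a Cd8a or Cd8b1 UMI by definition, so their share is high by construction, while the GP66+ cells were not gated.

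**Figure D3:**
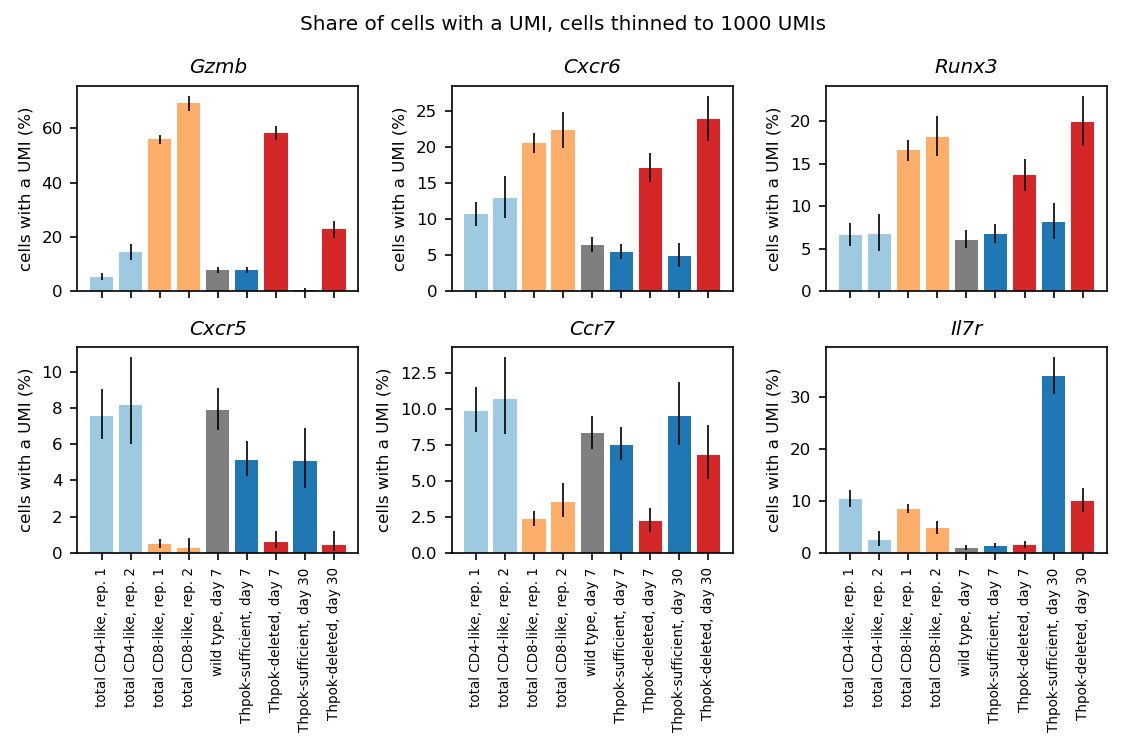
Bars give the percent of cells with a UMI of 6 genes after thinning to 1000 UMIs, in the CD4-like and CD8-like cells of the 2 total libraries and in the 5 GP66+ libraries, with exact binomial 95% intervals. Gzmb, Cxcr6 and Runx3 are more frequent and Cxcr5 and Ccr7 less frequent in the Thpok-deleted library of each day than in the sufficient one.

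Clustering the 5 GP66+ libraries together gave a Tfh-like cluster that held 21.8% (95% interval 20.1 to 23.6) of wild type and 17.5% (95% interval 15.9 to 19.2) of Thpok-sufficient cells at day 7, and a Th1-like cluster that held 8.50% (95% interval 7.37 to 9.74) and 7.62% (95% interval 6.53 to 8.83). Exact binomial intervals cover counting error only. The other clusters were mostly made of 1 library each, so that their sizes are not compared. A memory-precursor-like cluster took 1029 of its 1038 cells from the wild type library, and an unnamed one that shared its markers took 1147 of 1187 from the Thpok-sufficient library. Unnamed clusters with Th1 or cytotoxic markers took 800 of 912 cells from the day 7 and 522 of 541 from the day 30 Thpok-deleted library, and one with Il7r took 688 of 770 from the day 30 Thpok-sufficient library. Unnamed clusters held 11.7% of wild type, 65.9% of Thpok-sufficient and 85.7% of Thpok-deleted cells at day 7, and 98.9% and 98.2% at day 30.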

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

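The tests of explanations in this part and the interaction test were chosen after the results were seen, while the gene and list calls and the thinned sums they draw on were planned. Some results stood out because the single libraries of one group moved one way and those of the other the opposite way, by at least 0.5 for lists and 1 for genes on the log2 scale, sizes set after the data were seen. The list differences were not tested. The 2 genes were in the test of the genotype by day interaction, which called 0 of 11338 genes (adjusted p = 0.628 for Ikzf2 and 0.696 for Wdr95). The median log2 ratio of day 30 over day 7 for inhibitory receptors was 0.83 in Thpok-deleted cells, against -0.76 in Thpok-sufficient cells and -0.60 with the wild type library as day 7 value. For the Treg list the ratio of Thpok-deleted over Thpok-sufficient cells was 1.40 at day 30, against -0.61 and -0.63 at day 7 with the sufficient and the wild type library. For myeloid markers it was 1.62 at day 30, against -0.50 and -0.66. The myeloid medians rest on 5 members at day 30, 3 up and 2 down, and on 8 at day 7, 3 up and 5 down. The Treg list also counted 8 members at day 30 and 7 at day 7. Inhibitory receptors counted 9 in Thpok-deleted and 8 in Thpok-sufficient cells, so that the sets compared are not the same. For Ikzf2, a transcription factor of regulatory T cells, the ratio was 1.09 at day 30, against -3.09 and -3.20 at day 7. Its levels were 169, 158 and 18.4 CPM in wild type, Thpok-sufficient and Thpok-deleted cells at day 7 and 90.3 and 193 CPM in Thpok-sufficient and Thpok-deleted cells at day 30. For Wdr95 the day ratio was -1.05 in Thpok-deleted cells, against 1.04 and 1.74 in cells with intact Thpok, which held 4, 7 and 2 Wdr95 UMIs in the wild type, the day 7 and the day 30 library.

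Signals outside the comparisons were also found. B-like and myeloid-like clusters held 2.75% (95% interval 2.37 to 3.16) of cells in total CD44high replicate 1 and 0.561% (95% interval 0.290 to 0.978) in replicate 2. In barcodes of at most 10 UMIs, Hbb-bs stood at 1230.3 CPM in the day 30 Thpok-deleted library, against 480.4 in the day 7 Thpok-sufficient library.

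Cd8a and Cd8b1 UMIs and cytotoxic genes in Thpok-deleted GP66+ cells could come from CD8+ T cells in the sort or from the GP66+ cells themselves. Of cells with a Cd8a or Cd8b1 UMI, 43.9% (190 of 433, 95% interval 39.1 to 48.7) of day 7 and 28.9% (22 of 76, 19.1 to 40.5) of day 30 also held a Cd4 UMI, against 8.44% and 12.6% in the total libraries, which argues against single CD8+ cells as the whole source of these UMIs. UMIs from outside the cells, at the 99th percentile of UMIs per barcode there and the upper bound of the Cd8a and Cd8b1 share in empty droplets, would give such a UMI to at most 0.113% and 0.285% of cells, while 32.8% (95% interval 30.3 to 35.4) and 10.3% (95% interval 8.22 to 12.8) held one, which argues against empty droplets as the source. Doublets of a CD8+ and a GP66+ cell were not tested. The level of Cd8b1 allows 5.05% CD8-like cells at day 7 (upper counting bound 5.43). The CD8-like level is that of total cells gated on a Cd8 UMI, which lowers this share. The 12 cytotoxic genes compared were chosen as past the threshold in these same libraries, and the level in Thpok-sufficient cells was not subtracted. They would need from 10.9% (Gzma) to 178%, with a median of 71.0% and a first quartile of 27.1%. These values argue against such cells as the whole source of those genes, if they express them as total CD8-like cells do. The lowest list median of either day was 3.00, which argues against a single library as the source, and 14 of 14 list members stayed past the threshold in sums thinned to one depth, which argues against depth. The expression of cytotoxic genes by cells without Thpok stays a hypothesis, with 1 library per genotype and day.

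Of 22 tested early-response and stress genes, 6 were called higher in GP66+ than in total CD4-like cells, and both list calls were lost with an estimated correlation (adjusted p = 0.206). That test had little power with 2 residual degrees of freedom. In 18 of the 22 both GP66+ libraries lay above both total libraries, and 1 parted total replicate 1 and the wild type GP66+ library from the others, which argues against a batch shared by these libraries as the whole cause. The stress list had a median log2 fold change of 2.69. Handling of the tetramer sort could raise such genes, and it cannot be told apart from antigen specificity, since every GP66+ library was sorted with the tetramer and no total library was.

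Total replicate 1 and the wild type GP66+ library share differences from the other library of their kind. Of 7381 genes, 11 were at least 4-fold apart in the same direction in both pairs and 1 in opposite directions, against 0.121 by independent lists, as a shared library or sequencing batch would give (Pearson r 0.25 and Spearman rho 0.11 across genes, which are not independent replicates). The total pair differs in sex, with Xist at 870.7 and 0 and the Y-linked Ddx3y at 0 and 49.97 CPM in replicates 1 and 2, so sex stays open for that pair. In the GP66+ pair both libraries held Ddx3y, at 81.5 and 64.6 CPM, so sex does not account for the differences shared by both pairs. The 11 genes had a median GC content of 57.8%, above the upper quartile of 54.4% over all genes, so GC content may take part, although across all genes it had a Spearman rho of -0.12 and 0.04 with the ratios of the pairs. No biological explanation other than sex was tested.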

How the results depend on the processing

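Alternatives chosen after seeing the data were the covariate for total replicate 1 and the wild type GP66+ library, the fit without cells called by Scrublet, clustering of each library alone and the interaction test. No named gene reversed its direction under an alternative where either fit passed the threshold. A change of direction where neither fit passed was counted as the same. Outside of left-out libraries, named genes kept the side of the threshold in 1409 cases, lost the threshold in 63 and passed it newly in 87. The fit of the 4 Cre-bearing libraries alone is counted there (33 the same, 9 newly passed), although it leaves out the wild type library. Outside of left-out libraries, counts of genes stayed within 1.5 times in 44 cases and moved in 24. The fit of the 4 Cre-bearing libraries alone is among these too. Keeping doublets, and for genotype and day keeping all called cells, gave the same cells as the main setting and are not among these cases. With a library left out, named genes kept the side of the threshold in 69, 93 and 109 cases for GP66+ against total, genotype and day, lost it in 30, 110 and 172, and passed it newly in 32, 10 and 0. For lineage these values have no test, and 41 were the same and 67 moved. Counts of genes were then the same in 3 cases and moved in 25. Single-library list medians were the same in 52 cases, moved in 35 and reversed in 3, marker shares moved in 81 of 90 cases and state shares in 6 of 9. The cause was not tested for any change below unless named.

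For CD8-like against CD4-like cells, DESeq2 called 752 and 585 genes, and edgeR without the replicate block 522 and 620. The block is the shared capture of both classes, and all 522 and 620 genes were among those called with it. Leaving out either library leaves no residual degrees of freedom, so values without a test were computed and no counts. For GP66+ against total CD4-like cells, DESeq2 called 128 higher and 39 lower, no low-count filter 437 and 325, the covariate 138 and 49, the gate of 2 UMIs 25 higher, and thinned sums 1 lower. For Thpok-deleted against Thpok-sufficient cells, DESeq2 called 258 higher and 219 lower, no filter 419 and 372, cells outside cycling clusters 174 and 70, and the 4 Cre-bearing libraries alone 252 and 165. The last is the same fit as the one without the wild type library. Stricter cells called 16 lower and cells with a Cd4 UMI or no Cd8 UMI 22 lower. DESeq2 and no filter each kept all 79 and 41 genes. For day 30 against day 7, stricter cells, with fewer cells kept, called 291 higher and 289 lower. With each library left out, counts ranged from 0 to 322 and 0 to 340 for GP66+ against total, 0 to 252 and 0 to 165 for genotype, and 0 to 1440 and 0 to 1465 for day. Where such a fit leaves an arm with 1 library, that library is assumed to vary like the others. The interaction test called 0 of 11338 genes (lowest adjusted p = 0.628, edgeR), with 759 at an unadjusted p under 0.05. No other tool was run for it. Its 1 residual degree of freedom is the difference between the wild type and Thpok-sufficient libraries of day 7.

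Of the list calls, adjusted p with an estimated correlation and by fry were 0.306 and 0.133 for the CD8 lineage, CD4 helper and cell cycle lists, 0.306 and 0.144 for Tfh and 0.361 and 0.173 for Th1 in the lineage comparison. For GP66+ against total they were 0.206 and 0.104 for early response and 0.206 and 0.132 for stress. For genotype they were 0.0636 with an estimated correlation for CD8 lineage and Th1, which fry kept (0.0407 and 0.00414), 0.263 and 0.120 for CD4 helper and 0.289 and 0.154 for Tfh. For day the estimated correlation gave 0.341 for memory, early response, stress, cell cycle and glycolysis, and fry 0.0634, 0.0532, 0.0490, 0.0490 and 0.0634.

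Single-library list medians with the wild type library as day 7 value were 3.24 for CD8 lineage, -2.69 for Tfh and 0.55 for cell cycle in the genotype ratio, and the memory list reversed from -0.36 to 0.12. In the day ratio of Thpok-sufficient cells they were -0.17 for Tfh and -3.61 for cell cycle, CD8 lineage reversed from -0.63 to 0.20, and Th1 from -0.18 to 0.034. A prior count of 0.5 gave -3.18 for Tfh at day 7. Plain CPM gave 3.21 for CD8 lineage and -0.73 for Tfh in the genotype ratio of day 30, and -0.75 and -0.37 in the day ratio of Thpok-sufficient cells. Depth limits shares. Unthinned, Gzmb shares in wild type, Thpok-sufficient and Thpok-deleted cells at day 7 and Thpok-sufficient and Thpok-deleted cells at day 30 were 14.9, 14.8, 87.5, 1.24 and 35.7%, and Cxcr5 shares 33.4, 25.9, 3.03, 8.97 and 2.04%. Thinned to 2000 UMIs, which leaves out the cells below that depth, Gzmb shares were 11.02, 11.3, 74.6, 0.809 and 27.9%, and Cxcr5 shares 14.0, 11.7, 1.30, 9.43 and 1.93%. Tfh-like shares of wild type and Thpok-sufficient cells were 19.0 and 14.1% at resolution 1.2, 10.4% of wild type cells with the library clustered alone and 24.8% of Thpok-sufficient cells after thinning. Th1-like shares of Thpok-sufficient cells were 6.501% at resolution 1.2 and 11.7% with the library clustered alone. Resolution 0.5 gave no Tfh-like or Th1-like cluster in the GP66+ libraries, thinning gave no Th1-like cluster, and the Thpok-sufficient library clustered alone gave no Tfh-like cluster, so no value was had there.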

Other observations

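The tests of overlap, correlation and joint detection in this part were chosen after the results were seen, while the gene calls they draw on were planned. The hypothesis was that the genotype difference in GP66+ cells follows the lineage difference in the total libraries, which share no library. Of 76 genes higher in Thpok-deleted cells and tested in both comparisons, 75 were higher in CD8-like cells, against 13.5 by independent lists. Of 37 lower genes, 37 were higher in CD4-like cells, against 6.73. None were called in opposite directions (0 and 0). Across 9701 genes the log2 fold changes had a Pearson r of 0.80 and a Spearman rho of 0.68, while those of day against lineage had -0.17 and -0.25, and genes are not independent replicates. These values are consistent with a shift of cells without Thpok along the difference between the lineages, with 75 and 37 genes on that side.

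In GP66+ cells with intact Thpok, cells with a Cd8a or Cd8b1 UMI held a Cd4 UMI in 75.8% (122 of 161) of wild type and 66.7% (98 of 147) of Thpok-sufficient cells at day 7, and cells without a Cd8 UMI in 73.0% and 66.2%. In Thpok-deleted cells of day 7 the share among cells without a Cd8 UMI was 45.7% (405 of 886). Foxp3 held 3 UMIs over the CD4-like cells of both GP66+ libraries of day 7. Xist stood at 870.7 CPM in total CD44high replicate 1, and the other 6 libraries held the Y-linked Ddx3y, from 49.97 to 217.2 CPM.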
